A study of Mus musculus with 6 samples.

How the data were processed

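The samples were 6 skin libraries of db/db mice, 3 treated with vehicle and 3 with vemurafenib for 16 days. Per the labels' protocols, RNA was purified on columns, poly(A) RNA was enriched, and stranded single-end libraries were made with a KAPA kit. The authors deposited 1 table of whole-number read counts per gene symbol, and per the submitters' processing notes the reads were handled with HISAT2 and HTSeq on mm10. Versions, the annotation and the strand setting of the counting are not given in the sources used here. The table holds 1 further column whose name matches no sample of the series, and it was not used. The deposited counts sum to between 14189 and 78434 per library, and intervals and floors cover counting error only. The floor given for a library is 3 counts over its total.

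Counts were analysed as deposited. Genes were kept by edgeR's filterByExpr (smallest count 10, smallest total 15), library sizes were the totals of all counted genes, and scaling was by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion and group as the only term, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, and the standard error is the log2 fold change over the square root of F. The common biological coefficient of variation was 0.327 and the median standard error 0.448 on the log2 scale. CPM are counts scaled to a TMM-adjusted library total of 1000000, and the floors use the unadjusted total. Gene lists for skin cell types, hair follicle parts, wound repair, RAF to ERK signalling and other cells were fixed before the data were examined, as were the design, the rule for named genes and all alternatives not described as added. Lists with at least 5 tested members entered camera (limma 3.58.1) with an inter-gene correlation preset at 0.01, and an estimated correlation and fry were alternatives. The totals of lists were added after seeing the data, because 477 genes covered few list members: members were summed per library, lists with at least 30 counts were tested with edgeR, and log2 totals with a pseudocount of 0.5 were compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 libraries is 0.1. Principal components used log2 CPM with a prior count of 2.

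The named genes were Araf and Braf, and 1 further gene of the rule is not reported here. To these were added the 6 genes with the largest rise and the 6 with the largest fall among those that pass, have a mean of at least 5 CPM and separate the groups, leaving out clone and predicted symbols. Because none passed, the 6 with the smallest unadjusted p on each side took their place and are given as values. In each list the members with the smallest p were named: 3 where the list passed as a set, otherwise 2 where a member passed and 1 where none did. Genes named outside this rule are said to have been chosen after their values were seen.

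The test was checked on simulated counts with the real library sizes and means, 200 genes changed and a dispersion of 0.1, in 10 runs of 487 to 522 tested genes. For vemurafenib against vehicle it called 93.3% of 4-fold and 32.6% of 2-fold changes, 2.14% of its calls were false, and a list shifted 2-fold was called in 10 of 10 runs. Simulated genes varied independently, whereas the correlation estimated within the 2 lists tested as sets was 0.778 and 0.696. A large share of the tested genes was changed in each run. These figures therefore need not hold for the real data, and false calls of sets were not measured in the simulation. Alternatives were other scalings (DESeq2 size factors, upper quartile, totals), DESeq2 1.42.0, limma-voom with and without sample weights, other filters, glmTreat against a fold of 1.5, the replicate number as a block, leaving out the 20 most abundant genes and leaving out each library. A filter of at least 10 counts in total was added after seeing the data.

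Gene positions, types and exons came from GENCODE M21 on the same build, in which 47966 of the 48377 symbols (99.2%) were found. Exons were merged per gene, and an overlap with exons of a gene on the other strand was recorded in bp. Densities are counts over merged exon length for genes at a single locus off the mitochondrial genome, leaving out Gm26917 and Gm42418, which lie at the ribosomal RNA repeat of chromosome 17 and took 2.62% to 7.79% of a library's counts. Their intervals resample genes 1000 times. Genes that overlap on opposite strands are reported as uncertain, with their partner. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps.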

Results

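Skin was profiled by poly(A) RNA sequencing in db/db mice, animals without a working leptin receptor that become obese and diabetic and close skin wounds slowly. The libraries were made after 16 days of treatment with vemurafenib, an inhibitor of mutant BRAF kinase, or with vehicle. The labels give vemurafenib at 1 uM, and there were 3 libraries per group. They do not say that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part. The counted totals were low: 22985, 14189 and 48798 in vehicle 1, 2 and 3, and 78434, 20796 and 38293 in vemurafenib 1, 2 and 3. Of the 48377 gene symbols listed, 16695 had a count in any library and 477 were counted deeply enough to be tested. CPM are counts scaled to a library total of 1000000. By counting error alone, a gene with no count can lie at up to 131, 211 and 61.5 CPM in the vehicle libraries. In the vemurafenib libraries the floors are 38.2, 144 and 78.3 CPM. These floors bound the counts under a gene's name and are no upper limit of its transcript where reads were counted under another name.

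The counts under a gene's name need not come from that gene's own transcript in these data. Gapdh, Eef1a1 and Actb, which rank among the most abundant mRNAs of most tissues, had 6, 15 and 47 counts over all 6 libraries. None of a list of 16 housekeeping genes reached the tested set, and together they held 0.111% of the counts. Xist, the long RNA that coats the inactive X chromosome (X:103460366-103483254, minus strand, mm10), had 35 counts, while Tsix on the plus strand of the same locus had 704. Gm37376, a 453 bp feature on the strand opposite Malat1 (19:5801941-5802393), had 1548 counts and Malat1 itself had 612. Long non-coding genes with at least 100 bp of exon opposite a protein-coding exon held 12.2 counts per kb, against 0.736 for those with no gene opposite, a ratio of 16.6 (95% bootstrap interval 14.1 to 19.9). The ratio lay between 14.1 and 18.3 in the single libraries. Among protein-coding genes the densities were 4.22 and 1.03 counts per kb. Of the 477 tested genes, 327 had at least 100 bp of exon opposite a protein-coding exon. The collagen genes Col1a1, with 2950 counts, and Col3a1, with 2790, had no exon overlap of 50 bp or more on the opposite strand.

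**Figure D1:**
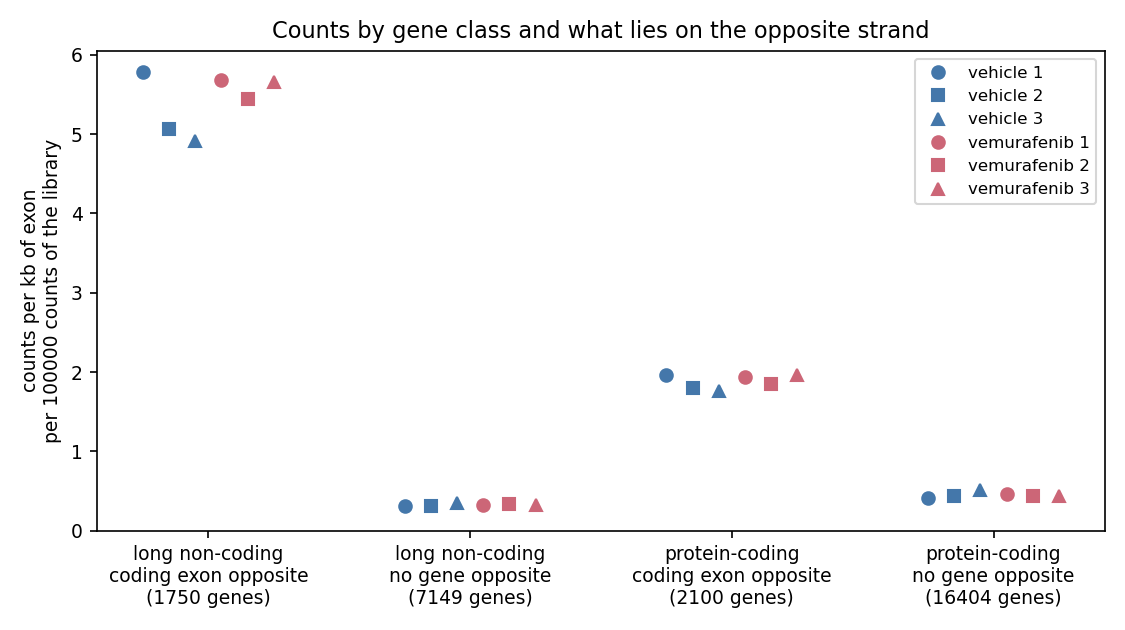
Counts per kb of exon, per 100000 counts of the library, for long non-coding and protein-coding genes with or without an exon on the opposite strand. Each point is a library, and in all 6 the long non-coding genes opposite a coding exon lie between 4.91 and 5.78 while those with no gene opposite lie between 0.311 and 0.348.

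The design asks what vemurafenib changed in the skin of the diabetic mice after 16 days. With a preset correlation, camera called collagen matrix genes lower and mitochondrial transcripts higher with vemurafenib as sets. All 12 tested collagen members lay below vehicle and all 7 tested mitochondrial members above it. Members of a list varied together (estimated correlation 0.778 and 0.696), so their shared direction is not 12 or 7 separate results. Neither set was called with an estimated correlation (adjusted p = 0.244 for both) or with fry (adjusted p = 0.31 for both). The totals of both lists overlapped between the groups. Some regroupings of the libraries that mix vehicle with vemurafenib also called 2 lists. Krt17, Dsp and Ppl had log2 fold changes of 2.02, 1.20 and 1.46, with adjusted p-values of 0.242, 0.874 and 0.874. No single gene passed the test. With edgeR, 0 of 477 genes reached an adjusted p under 0.05 (0 higher and 0 lower), and the lowest adjusted p was 0.242. An unadjusted p under 0.05 was reached by 23 genes, 12 higher and 11 lower, where chance alone gives 23.85. DESeq2 and limma-voom also called 0 genes, with 14 and 40 genes at an unadjusted p under 0.05. The groups did not overlap for 42 genes, or 8.81%, where chance gives 10%. With looser filters on low counts edgeR called 2 or 3 genes, all higher with vemurafenib, and without vemurafenib 1 it called 2. Gm12744 and Gm43937 were called in each of these cases, and these 2 features were named after their values were seen.

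Braf, the drug's target, and the related kinase gene Araf were too thinly counted to test. Araf (X:20797814-20860519) and Braf (6:39603237-39725463, opposite Ndufb2) had 5 counts each over the 6 libraries. So few counts can show neither a difference nor its absence. The list of 11 RAF, MEK, ERK and RAS genes had 431 ± 142 CPM with vehicle and 373 ± 42.9 CPM with vemurafenib in total (SD, n = 3). Transcripts known to follow ERK activity, such as Dusp6, Spry4 and Etv4, had 409 ± 70.4 and 411 ± 60.1 CPM as a list of 20, a log2 fold change of 0.03 ± 0.48 (SE). That list held 88 counts in all, 29 of them under Ccnd1, while Dusp6, Spry4 and Etv4 had 3, 0 and 3. Its total therefore says little about those 3 genes. Immediate early genes, among them Fos and Egr1, had 433 ± 226 and 645 ± 325 CPM, a log2 fold change of 0.55 ± 0.58, which was 0.22 without vemurafenib 1 and 1.11 without vehicle 3. None of these 3 lists had a tested member, and none of their totals passed.

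In the epidermal lists no gene passed over all genes. Krt17, a keratin of the wound edge and the hair follicle (11:100256217-100261029), had 176 ± 121 CPM with vehicle and 574 ± 249 CPM with vemurafenib, a log2 fold change of 2.02 ± 0.56 (adjusted p = 0.242). The 3 vemurafenib libraries all lay above the 3 vehicle libraries, the value was 1.33 without vehicle 3, and reads shared with closely related keratins cannot be excluded. Dsp, the desmoplakin of desmosomes (13:38151294-38198577, opposite Gm10129), had 646 ± 339 and 1391 ± 454 CPM, a log2 fold change of 1.20 ± 0.47 (adjusted p = 0.874). Ppl, the periplakin of the cornified envelope (16:5086291-5132421), had 181 ± 157 and 421 ± 177 CPM, with overlapping groups. Dsp and Ppl are on none of the fixed lists. Krt17 was the single tested member of the wound-edge keratinocyte list and passed when adjusted over the list alone, with an adjusted p of 0.242 over all genes. That list totalled 1228, 1470 and 151 CPM in vehicle 1, 2 and 3 and 1699, 1221 and 2587 CPM in vemurafenib 1, 2 and 3, a log2 fold change of 1.00 ± 0.62 that was 0.45 without vehicle 3. In the basal layer list 3 members were tested and 0 passed, over all genes and adjusted over the list alone. Its leading member Krt14 (11:100203162-100207548) had a log2 fold change of 0.78 ± 0.61, which was 0.16 without vehicle 3 and 1.87 without vehicle 2. The list totalled 2148 ± 550 and 2873 ± 402 CPM. In the list of cornification genes 4 members were tested, 0 passed on either adjustment, and Sbsn (7:30751471-30756134) had the smallest p with a log2 fold change of 0.27 ± 0.49. The value of Sbsn turned negative without vehicle 1 (-0.09) and without vemurafenib 3 (-0.19).

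Of the other genes with the smallest p on the higher side, each had exons of another gene on its opposite strand. Mindy1 (3:95281345-95296166), opposite Anxa9 and Prune1, had a log2 fold change of 1.04 ± 0.44. Zmynd15 (11:70459433-70466202), opposite the chemokine gene Cxcl16, had 1.17 ± 0.49, which was 0.74 without vehicle 3 and 1.45 without vehicle 1. Mterf4 (1:93299211-93305915), opposite Sned1, had 1.33 ± 0.57, which was 0.79 without vehicle 1. On the lower side Tmem198b (10:128800036-128804370) had the smallest p of all tested genes, with 994 ± 138 CPM with vehicle and 281 ± 212 CPM with vemurafenib. Its log2 fold change was -1.97 ± 0.49 (adjusted p = 0.242), every vemurafenib library lay below every vehicle library, and its exons lie opposite those of Mmp19 and Dnajc14. Serinc4 (2:121439059-121456781), opposite Serf2 and Hypk, had -1.37 ± 0.43, and Med12l (3:59005825-59318682), opposite Igsf10, had -1.35 ± 0.48. Mtss1l (8:110721476-110741400), with no such overlap, had 548 ± 137 and 266 ± 109 CPM, a log2 fold change of -0.99 ± 0.43. All of these except Tmem198b had an adjusted p between 0.493 and 0.874.

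**Figure D2:**
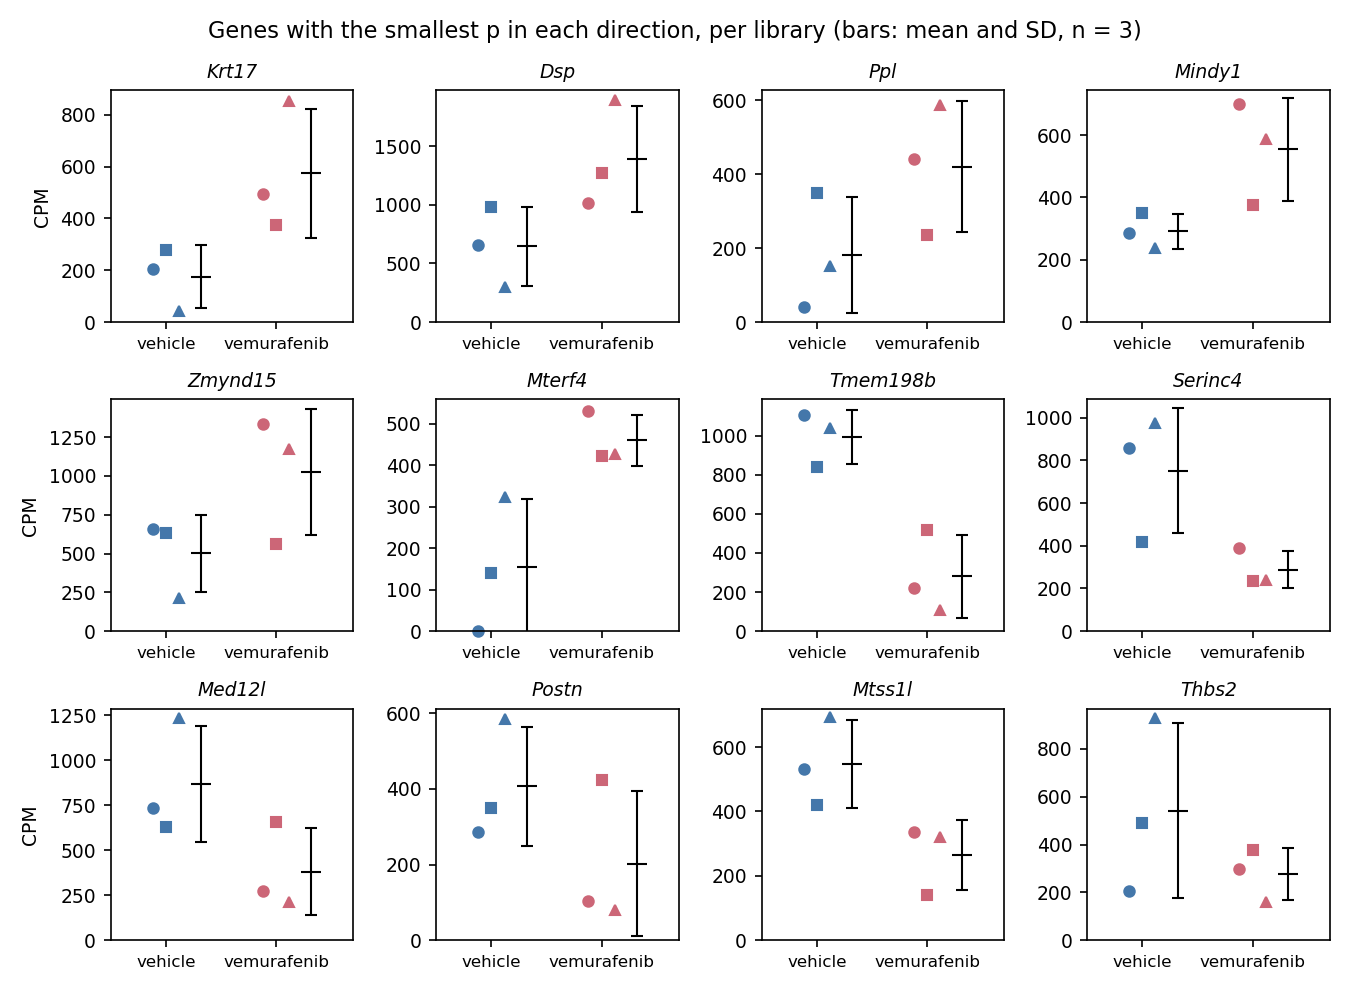
Normalised CPM of the 6 genes with the smallest p on each side, per library (blue, vehicle; red, vemurafenib; circle, square and triangle for libraries 1, 2 and 3), with the mean and SD of each group. Tmem198b separates the groups, with means of 994 and 281 CPM, while for Ppl, Zmynd15, Med12l, Postn and Thbs2 the groups overlap.

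The collagen and fibroblast list was called lower with vemurafenib as a set (camera with a preset correlation of 0.01, adjusted p = 4.85e-05). Its median log2 fold change was -0.56 over 12 tested members. With an estimated correlation the set gave adjusted p = 0.244, and the correlation itself was 0.778. None of the 12 members passed alone, over all genes or adjusted over the list alone. Thbs2, a thrombospondin that binds collagen fibrils (17:14665500-14694235), had 542 ± 366 CPM with vehicle and 278 ± 109 CPM with vemurafenib, a log2 fold change of -1.09 ± 0.49. Col6a3 (1:90765923-90843971) had 2849 ± 1114 and 1428 ± 559 CPM (-0.99 ± 0.45), and Col5a2 (1:45374321-45503282) had 2074 ± 1532 and 1052 ± 408 CPM (-1.01 ± 0.50). Without vehicle 3 the value of Col5a2 was -0.15. The fibrillar collagens with most counts had smaller values, -0.75 ± 0.49 for Col3a1 and -0.55 ± 0.49 for Col1a1. The list totalled 37607, 54249 and 85006 CPM in vehicle 1, 2 and 3 and 43021, 49485 and 23199 CPM in vemurafenib 1, 2 and 3. The set was no longer called without vehicle 3 or without vemurafenib 3. Vehicle 3 and vemurafenib 3 were also the 2 ends of the first principal component (35.6% of the variance), which did not separate the groups (exact permutation test, two-sided, p = 0.4, with 0.1 the smallest p possible). Of myofibroblast and scar genes 1 was tested: Postn, the matrix protein periostin (3:54361109-54391037), had 407 ± 157 and 202 ± 191 CPM, a log2 fold change of -1.38 ± 0.59 (adjusted p = 0.874), which was -2.15 without vemurafenib 2. As the only tested member it passed when adjusted over the list alone, there and in the list of bulge genes. The scar list totalled 1792 ± 570 and 1256 ± 491 CPM, and the list of matrix proteases and their inhibitors 1181 ± 908 and 875 ± 277 CPM.

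Mitochondrial transcripts were called higher with vemurafenib as a set (camera with the same preset correlation, adjusted p = 0.00288). Their median log2 fold change was 0.47 over 7 tested members. With an estimated correlation the set gave adjusted p = 0.244. None of the 7 passed alone or adjusted over the list alone. The subunits of NADH dehydrogenase mt-Nd2 (M:3914-4951) and mt-Nd4 (M:10167-11544) had log2 fold changes of 0.94 ± 0.43 and 0.79 ± 0.44, and mt-Cytb (M:14145-15288) had 0.47 ± 0.41. The light-strand gene mt-Nd6 had 368 counts, more than the 164 of the abundant mt-Co1, with log2 fold changes of 0.06 ± 0.46 and 0.12 ± 0.46. The list totalled 18742, 9170 and 9736 CPM in vehicle 1, 2 and 3 and 14185, 18827 and 16639 CPM in vemurafenib 1, 2 and 3. Of its 3158 counts 1754 were under mt-Nd5, which had a log2 fold change of 0.35 ± 0.46. The log2 fold change of the total was 0.40, from 0.22 without vehicle 2 to 0.81 without vehicle 1. The call was lost without vehicle 2, vehicle 3 or vemurafenib 2.

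**Figure D3:**
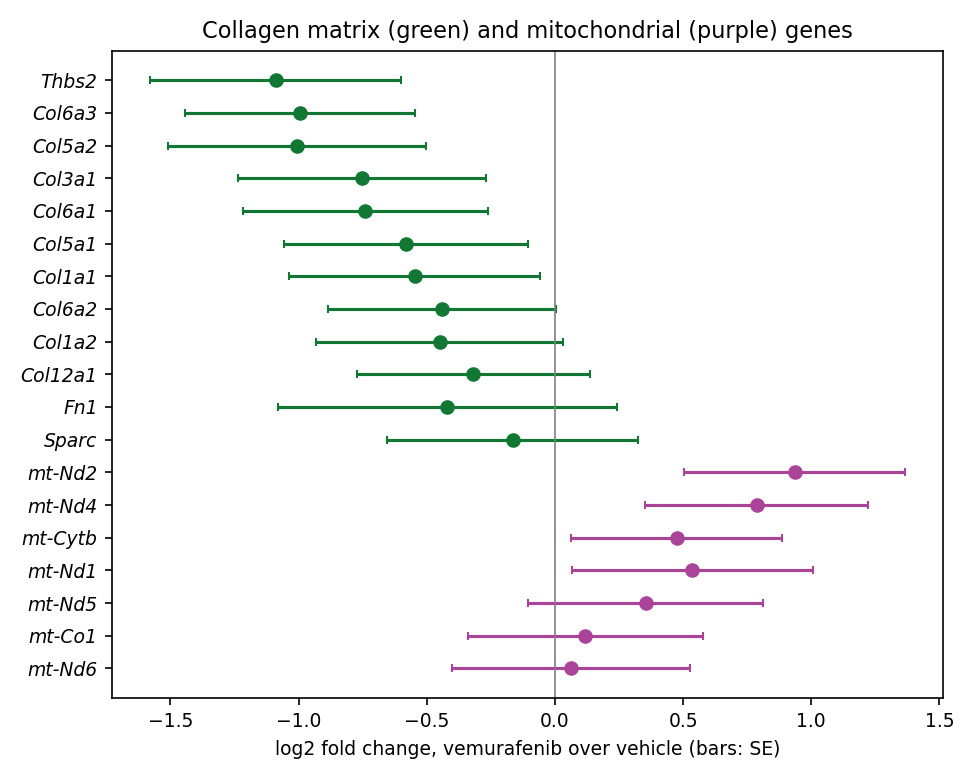
Log2 fold change of vemurafenib over vehicle with its standard error for the tested genes of the collagen matrix list (green) and the mitochondrial list (purple). The 12 collagen matrix genes lie between -1.09 and -0.17 and the 7 mitochondrial genes between 0.06 and 0.94, and for 8 of the 19 genes the error bar crosses zero.

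Hair follicle regeneration is part of the study's subject, and most follicle genes were at the edge of detection. Genes of the inner root sheath, the layer that guides the growing hair, totalled 7733 CPM in vemurafenib 3 and between 130 and 560 CPM in the other 5 libraries. Tchh, the trichohyalin of that layer (3:93442330-93449077), had 245 counts there and 6, 7, 2, 13 and 3 in vehicle 1, 2, 3 and vemurafenib 1 and 2. Krt71, Krt25 and Krt27, keratins of the same layer, had 23, 9 and 8 counts in vemurafenib 3 and at most 1 elsewhere. Tchh and these keratins were named after their values were seen. The list's log2 fold change was 3.16 ± 2.04, and without vemurafenib 3 it was -0.64. Hair matrix regulators totalled 174 ± 74.5 and 326 ± 254 CPM, a log2 fold change of 0.79 that was -0.17 without vemurafenib 3. Genes of the bulge, where follicle stem cells sit, totalled 688 ± 314 and 592 ± 229 CPM. Wnt targets had 240 ± 225 and 241 ± 76.7 CPM and Hedgehog pathway genes 116 ± 68.8 and 192 ± 38.5 CPM. The sebaceous gland list had 368, 350 and 476 CPM with vehicle and 454, 892 and 1360 CPM with vemurafenib, a log2 fold change of 1.14 ± 0.64 that was 0.66 without vemurafenib 3. Hair shaft keratins had 3 counts in all, keratin-associated proteins 1 and dermal papilla genes 21, too few for a comparison.

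**Figure D4:**
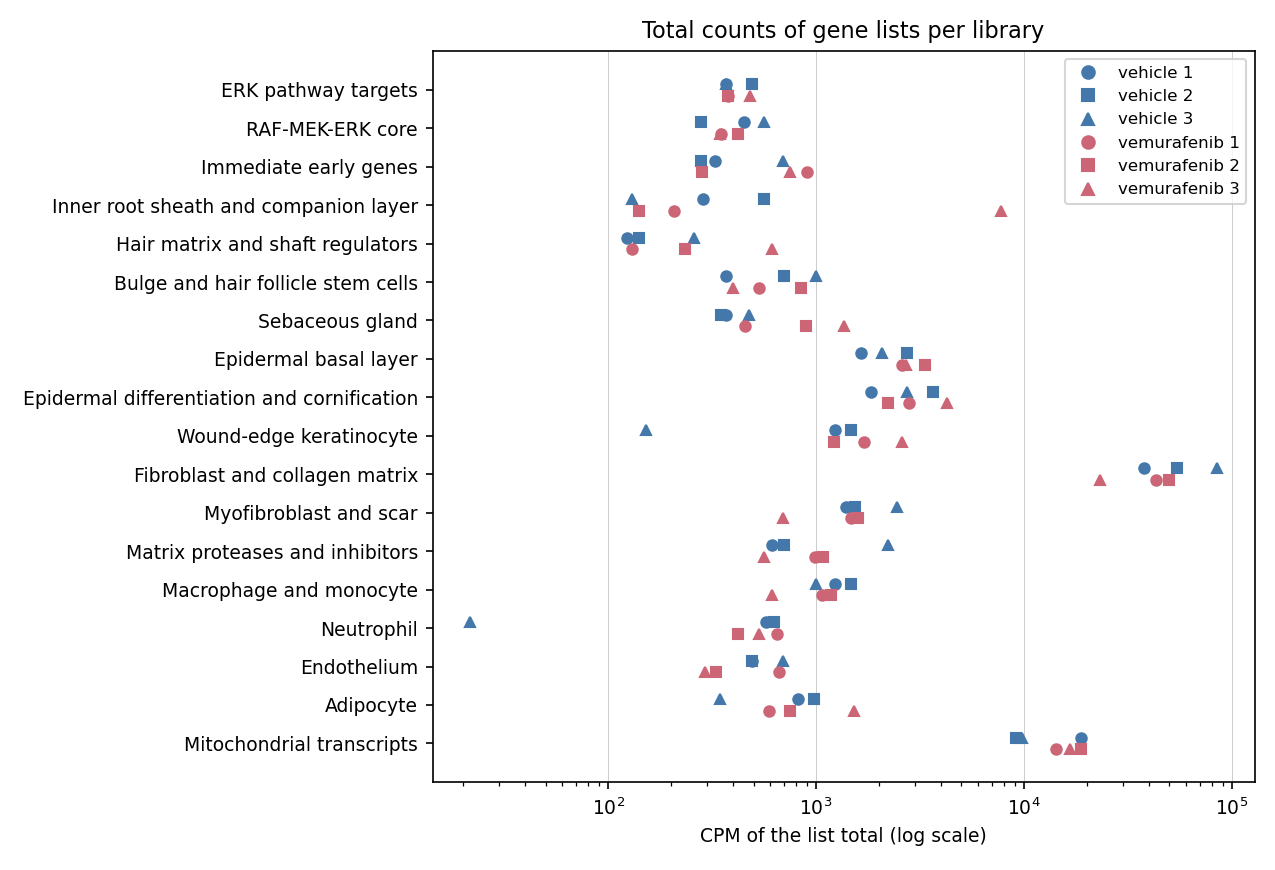
Summed CPM of 18 gene lists in each library on a log scale (blue, vehicle; red, vemurafenib; circle, square and triangle for libraries 1, 2 and 3). The groups overlap in each list shown, and inner root sheath genes stand at 7733 CPM in vemurafenib 3 alone.

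Of the 37 lists, 29 had at least 30 counts, and 0 of their totals passed with edgeR (0 at an unadjusted p under 0.05, lowest adjusted p 0.842). In 0 of the 29 did the totals separate the groups. Leaving out 1 library changed the sign of the log2 fold change of the total in 14 of the 29 lists. Without vemurafenib 3 it changed in 8: inner root sheath, hair matrix, cornification (0.18 to -0.12), adipocyte (0.46 to -0.04), growth factor (0.19 to -0.15), ERK target, proliferation and heat shock genes. Without vehicle 3 it changed in 5: Wnt targets (-0.18 to 1.11), matrix proteases (-0.47 to 0.41), bulge genes (-0.26 to 0.16), ERK targets (0.03 to -0.04) and neutrophil genes (0.53 to -0.14). Macrophage and monocyte genes had 1231 ± 237 CPM with vehicle and 950 ± 297 CPM with vemurafenib, and neutrophil genes 408 ± 336 and 535 ± 113 CPM. T cell genes had 385 ± 52.3 and 210 ± 130 CPM, a log2 fold change of -0.73 that was -1.35 without vemurafenib 1. Foxp3 (X:7573644-7595245), on the strand opposite Ccdc22 and Ppp1r3f, held 54 of the 67 counts of that list. Dendritic and Langerhans cell genes had 119 ± 106 and 246 ± 125 CPM, and interferon response genes 134 ± 122 and 198 ± 105 CPM. Endothelial genes had 558 ± 117 and 428 ± 203 CPM, and growth factors of wound repair 396 ± 259 and 464 ± 288 CPM. Proliferation genes had 376 ± 31.3 and 374 ± 162 CPM, a log2 fold change of 0.02 ± 0.50, and heat shock genes 417 ± 82.5 and 425 ± 178 CPM. Among other tissues, adipocyte genes had 715 ± 329 and 956 ± 495 CPM, skeletal muscle genes 668 ± 288 and 424 ± 72.1 CPM, nerve and Schwann cell genes 364 ± 142 and 282 ± 152 CPM, and red blood cell genes 193 ± 101 and 201 ± 29.4 CPM. Lipe, the hormone-sensitive lipase (7:25379527-25398710) and the only tested adipocyte gene, had a log2 fold change of 0.65 ± 0.62, which was -0.33 without vemurafenib 3, and it passed on neither adjustment. Inflammatory cytokines had 26 counts, mast cell genes 17, and B cell and lymphatic genes 6 each, too few for a comparison. Melanocyte genes had 21 counts, under the minimum for a test, at 52.2 ± 45.9 CPM with vehicle and 126 ± 19.6 CPM with vemurafenib, and the groups did not overlap.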

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

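The filter of at least 10 counts in total was chosen after the data were seen; the other alternatives were not. The count of 0 changed genes with edgeR was kept under the other scalings, DESeq2, both forms of limma-voom, glmTreat and without the 20 most abundant genes. It became 3, all higher, with no filter beyond 1 count (Gm12744, Gm43937, Pitx3), 2, both higher, with at least 1 CPM in 3 libraries, and 3, all higher, with a total of at least 10 (Gm12744, Gm43937, 2310002F09Rik), where DESeq2 called 0. Leaving out 1 library gave 0 to 2 changed and 0 to 2 higher genes, the 2 without vemurafenib 1. The cause was not tested. The first filter moved the median log2 fold change of the 477 genes to 0.23 and the next to 0.18, from 0.02. Gm12744 had a log2 fold change of 2.28 and an adjusted p of 0.242, and over its alternatives the adjusted p ran from 0.000374 to 0.997. The 2 lists called as sets became 5 with no filter, 3 with at least 1 CPM, 4 with a total of at least 10, 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and a total of at least 10, and 0 to 2 when leaving out 1 library: 0 without vehicle 3, 1 without vemurafenib 2 and 1 without vemurafenib 3. Without vehicle 2 the epidermal basal list took the place of the mitochondrial list. Mean list levels separated the groups for 1 list, the wound-edge keratinocyte list, through its 1 tested member Krt17, while its total overlapped, and for 4, 5 and 4 lists with no filter, at least 1 CPM and a total of at least 10. Over the named genes 375 of the recomputed values kept direction and side of the threshold. Leaving out 1 library gave Sbsn log2 fold changes from -0.19 to 0.58 and Lipe from -0.33 to 1.10, with the negative values named in the report. With the replicate number as a block in edgeR 0 genes were called (22 at an unadjusted p under 0.05, lowest adjusted p 0.0648) and 2 lists. Libraries of the 2 groups that share a number deviated from their group means with correlations of 0.04, -0.08 and -0.33. Those with different numbers ranged from -0.25 to 0.32. So few values neither show nor exclude a pairing, and the labels do not say what a number marks. The low counted totals limit the tested set to 477 of 16695 genes with a count. Whether they come from the depth of sequencing or from the counting was not tested.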

Other observations

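All tests in this part were chosen after the values they explain had been seen. Several genes outside the tested set had counts in the vemurafenib libraries and few or none with vehicle, given here as counts in vehicle 1, 2, 3 and vemurafenib 1, 2, 3. Gm43937 (6:88784330-88787451), a feature of unconfirmed type inside the monoglyceride lipase gene Mgll and on its other strand, had 3, 0, 3 and 18, 33, 43. With a total of at least 10 counts as the filter, edgeR gave it a log2 fold change of 3.63 ± 0.62 (adjusted p = 1.74e-05). 2310002F09Rik (7:43695209-43797958), opposite exons of the kallikreins Klk8 and Klk14, had 4, 3, 0 and 48, 6, 26 (adjusted p = 0.0393). Pitx3 (19:46135685-46148326) had 0, 0, 0 and 0, 11, 20 (adjusted p = 0.0748), and its exons overlap by 10 bp the end of Elovl3, a fatty acid elongase of sebaceous cells. Klk7, a protease of the stratum corneum, had 0, 0, 0 and 9, 2, 10 (adjusted p = 0.0956). Krt79, a keratin of the sebaceous duct, had 0, 0, 0 and 5, 1, 10 (adjusted p = 0.240). Scd1, a desaturase of sebaceous lipid synthesis, had 0, 0, 0 and 0, 3, 11 (adjusted p = 0.255), and S100a8 0, 0, 0 and 5, 3, 5 (adjusted p = 0.407). On the lower side none passed: Slc7a15 had the smallest p, with 4, 1, 16 and 2, 0, 0 (adjusted p = 0.0559), and Gpnmb had 8, 7, 14 and 1, 6, 2 (adjusted p = 0.240). With that filter DESeq2 called 0 genes (58 at an unadjusted p under 0.05), and the epidermal basal and wound-edge keratinocyte lists were higher as sets (camera, adjusted p = 0.0188 and 0.00146), both with adjusted p = 0.369 with an estimated correlation.

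The first pattern is that counts do not follow the strand of abundant genes, and a candidate explanation is that reads of these stranded libraries were counted on the strand opposite to their transcript. It needs non-coding genes opposite a coding exon to be dense, and their density was 16.6 times that of non-coding genes with no gene opposite (interval 14.1 to 19.9). Unstranded background such as genomic DNA as the main source would read both strands alike, yet the non-coding member was denser in 90.6% of 661 overlapping pairs with at least 20 counts (Wilson 95% interval 88.2% to 92.6%). Low depth alone would thin both members of a pair alike and leave the coding one denser, as deep libraries of poly(A) RNA have it, and the same 90.6% speaks against that too. Of these explanations, opposite-strand counting is the only one the values go with. It stays a hypothesis, because the reads were not recounted with another strand setting, and no biological explanation was tested. It does not by itself account for the 2950 counts under Col1a1, which had no exon overlap of 50 bp or more on the opposite strand. Under opposite-strand counting, Gm26788 may stand for Dst, Gm9913 for Fbn1 and Tmem198b in part for Mmp19.

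The second pattern is the inner root sheath signal of vemurafenib 3. Depth of that library does not account for it, since the list took 0.757% of its counts (exact 95% interval 0.673% to 0.849%), 13.4 times the share in the highest other library (interval 6.73 to 31.4). The other 2 vemurafenib libraries had 207 and 141 CPM of it, between the lowest and the highest vehicle library. More hair-bearing skin or active follicles in that piece of tissue may account for it, and the lists go both ways. Of the 5 other fixed lists of follicle parts and pathways with at least 30 counts, 2 were highest in the same library, hair matrix and sebaceous gland, as were adipocyte genes. Bulge genes (400 CPM), Wnt targets (187 CPM) and Hedgehog genes (160 CPM) were not, so the explanation stays open. Gm43352, opposite the start of the hair matrix regulator Lef1, had 18 of its 21 counts there. A response to vemurafenib in 1 sample stays open, because a piece of skin with more growing follicles and a treated sample that formed them look alike here.

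The third pattern is that Gm12744 and Gm43937 were higher with vemurafenib where low counts were filtered less strictly. Gm12744 had 14, 12, 10 and 58, 69, 127 counts. Scaled for depth it had 543 ± 313 CPM with vehicle and 2459 ± 1480 CPM with vemurafenib, and the groups overlapped. Gm43937 lies in a gene of lipid metabolism, Mgll, which itself had 0, 1, 2 and 1, 5, 12. A candidate explanation is that sebaceous gland genes rose, read in part from the opposite strand. The fixed sebaceous list together with the features opposite its members had 368, 350 and 563 CPM with vehicle and 454, 1502 and 2027 CPM with vemurafenib. The groups overlapped through vemurafenib 1 (exact permutation test, two-sided, p = 0.2), so the explanation stays open, limited by 3 libraries per group. The added features held 42 counts, 31 of them under Pitx3, which was already named for its values and overlaps Elovl3 by only 10 bp. What they add is therefore no separate evidence, and the list alone had 454, 892 and 1360 CPM with vemurafenib.

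Features on the opposite strand of list members were also summed for the 21 lists where they held at least 30 counts. The groups separated in 1 of the 21 lists, where chance gives 10%. The exception was the ERK target list, whose 5 opposite-strand features, with exons opposite Dusp5, Spry1, Phlda1, Fosl1 and Spred3, had 498 ± 149 CPM with vehicle and 934 ± 92.9 CPM with vemurafenib. The log2 difference was 0.91 (exact permutation test, two-sided, p = 0.1, the smallest possible, and 0.817 after adjustment over 21 lists). The counts under the names of the ERK target genes themselves stood at 409 and 411 CPM.

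The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real count of changed genes was 0, so that all 10 give at least as many by construction, and the highest other split gave 3. That split sets vehicle 1, vehicle 3 and vemurafenib 1 against the rest and has 64 genes at an unadjusted p under 0.05 against the real 23. For lists changed as sets, 3 of the 10 splits gave as many as the real 2, and the highest other gave 2. The other splits called 0, 0, 1, 1, 1, 0, 1, 2 and 2 lists. A set call at the preset correlation therefore does not by itself mark the treatment.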
